A study of Caenorhabditis elegans with 51 samples.

How the data were processed

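Small RNA of Caenorhabditis elegans young adults was sequenced in 51 samples, of which 6 entered the comparisons. These 6 libraries came from 1 strain, which carried a fragment of oma-1 inside the retrotransposon Cer3, an epitope-tagged HRDE-1 and an epitope-tagged CSR-1. HRDE-1 and CSR-1 are Argonaute proteins, which bind small RNAs. Small RNA that came down with either protein (small RNA immunoprecipitation, sRIP) was sequenced beside the input, with 2 libraries of each kind according to the labels. Per the labels' protocols, libraries were made by ligation after treatment with a phosphatase and a polynucleotide kinase. The other 45 samples belong to a second table, whose 45 value columns carry library codes that the labels used here do not tie to a sample. That table was therefore not used here, and the planned comparisons of inserted genes, of oma-1 deletion, of P granule, Argonaute and piRNA pathway mutants, of CSR-1 depletion, of single-library mutants, and of the HRDE-1-bound and CSR-1-bound gene lists in total small RNA were not analysed here.

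The deposited values of the 6 libraries are RPKM, reads normalised to gene model length and library size, calculated by the authors for 20938 gene models. Per the submitters' processing notes, Bowtie 1.2.3 was among the tools. The genome build, the annotation, the strand counted, the read lengths kept and the treatment of reads that map to several places are not given in the sources used here. All 80624 values above 0 came out as whole reads (100%, tolerance 1e-06 of the value) once a library total and 1 whole model length per gene were deduced from the values. Deduced lengths are the shortest that give whole reads, so the 100% is a weak check of these lengths. For 469 models that length was under 0.6 of every annotated length of the gene and was raised to a multiple, a rule added after an implausible length was seen. Reads of models with no annotated counterpart are therefore minimum numbers. Of the models above 0 with an annotated coding length, 23.2% had a final length equal to it. The comparison of replicates below, read numbers, floors, intervals, simulations, voom weights and the test by gene length use these deduced values, while printed RPKM and fold changes do not.

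The deduced library totals were 2728020 and 2104162 reads for the input, 4872549 and 3248065 for HRDE-1 and 4992358 and 2991634 for CSR-1. Reads on gene models made up 49.7% and 51.6% of the input totals, 48.4% and 50.4% of the HRDE-1 totals and 39.2% and 42.1% of the CSR-1 totals. A group with 0 reads was given a floor of 3 reads over the group, and folds against it are written as bounds. No bound was set where the other group had 3 reads or fewer, or where the bound did not exceed 1. Such genes kept their fold on RPKM + 1 in list medians. A ratio that rests on 1 to 3 reads is given with its exact 95% counting interval. Floors and intervals cover counting error only, because reads without molecular identifiers are not independent molecules.

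Replicates were compared before averaging with a chi-square test of the deduced reads across genes. The input pair differed by no more than sampling noise (chi-square per degree of freedom 0.999 over 8152 genes, p = 0.514). The HRDE-1 pair differed by more (2.04 over 9273 genes). The CSR-1 pair did so slightly, at 1.07 over 7394 genes, with a chi-square p of 5.83e-06. The input pair was therefore counted as 1 sample with the mean RPKM of both libraries. That departs from the plan, which had 2 input samples, and the planned version is given among the alternatives. Whether other input pairs differ could not be checked, since the input has 1 pair. The fit then held 5 samples in 3 groups with 2 residual degrees of freedom, and the lone input was assumed to vary like the other groups. No label says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

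For models that share a symbol (610 symbols), the model with the highest mean RPKM was kept, which left 20202 genes. Genes with an RPKM of at least 1 in 2 or more libraries were tested (10908 genes). limma 3.58.1 in R 4.3.3 was fitted to log2(RPKM + 1) with a trended prior (prior degrees of freedom 2.8), 1 mean per group and two-sided moderated tests. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison. A gene was called higher or lower with an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes with low values. HRDE-1 against CSR-1 was added as a further contrast of the same fit after the data were seen. On reads simulated for 10392 genes of the HRDE-1 comparison, the fit called 85% of 100 genes changed 3-fold and 100% of 100 genes changed 6-fold. It made 6 false calls among 10192 unchanged genes. The changed genes all had an input RPKM of at least 5, so these rates do not cover genes with lower values. The extra dispersion between replicates was assumed to be 0.01 in every library. The false calls therefore do not cover a pair that varies more than another, as the HRDE-1 pair did.

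The design, the threshold, the lists and the rule for named genes were fixed before the data were examined. Of 18 gene lists, 14 had at least 5 tested genes: oogenic and maternal RNA regulators, P granule components, meiotic chromosome genes, Argonautes and small RNA pathway genes, spermatogenesis genes, histones, ribosomal proteins, targets of ERGO-1 class siRNA, genes that gave germline-expressed Cer3 inserts, and muscle, neuronal, intestinal, cuticle collagen and heat shock genes. The genes that gave soma-expressed inserts had 2 tested members, microRNA genes 1, and 21U-RNA and ribosomal RNA genes 0, so these lists were not tested. Lists were tested with camera in limma at a preset correlation of 0.01, two-sided, adjusted over the 14 lists. A second run estimated the correlation between genes from the data, with only the 2 residual degrees of freedom of the fit. Its losses cannot be put down to correlation alone. Collagen genes had an estimated correlation of −0.0145, below the preset, yet their camera p in CSR-1 rose from 7.39e-05 to 0.0447. Inserted germline and spermatogenesis genes also lay below the preset, at −0.00924 and 0.00606. The other lists lay above it. Intestinal genes had 0.523, oogenic 0.419, small RNA pathway 0.289, ERGO-1 class 0.229, meiotic 0.223 and P granule genes 0.216. For these lists the p-values at the preset may be too small. The genes named are the precipitated proteins' own genes, all genes inserted into Cer3 in any strain, the 8 largest rises and 8 largest falls per comparison with input, and up to 3 called members of each list past the threshold. The rises and falls were taken from calls with both libraries on the same side and a mean RPKM of at least 5 in the higher group. The paralog oma-2, and any gene named outside this rule, was chosen after its values were seen.

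Alternatives planned beforehand were a pseudocount of 0.1, no filter on low values, centring of library medians, leaving out each library, a block for the replicate number and an estimated correlation for the lists. The fit with 2 input samples, the planned one, became an alternative once the input pair was merged, and libraries were left out in both forms of the fit. Alternatives chosen after seeing the data were every gene model as its own row, setting the median log2 ratio to the input to 0 (chosen after the result of centring library medians was seen) and voom weights on deduced reads. Random lists matched on input level and the tests by chromosome were added then too. Because both precipitations were compared with the same input, 50 simulations of unchanged precipitations gave the correlation that a shared input produces without any change. Their overlap of calls was bound to be near 0, since no gene was changed.

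The library codes of the replicates differ in their prefix, a possible batch, and each prefix holds 1 library of each kind. A test within a prefix was not possible, and ratios within each replicate number are given instead. Positions are those of the WBcel235 annotation, to which 20340 of the 20938 models matched by sequence name. They serve only to locate genes, since the authors' build is not given in the sources used here. Of 88 named genes, 14 overlapped another gene on the opposite strand and 7 on the same strand. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.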

Results

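The data were small RNA libraries of C. elegans young adults from a strain in which the retrotransposon Cer3 carries a fragment of oma-1, a gene for a zinc finger protein of oocyte maturation. Small RNA precipitated with HRDE-1 and with CSR-1 was compared with the input. HRDE-1 is a nuclear Argonaute of heritable germline silencing, and CSR-1 an Argonaute known to bind siRNAs against germline-expressed genes. The labels give 2 libraries each of input, HRDE-1 sRIP and CSR-1 sRIP, with library totals from 2104162 to 4992358 reads. The 2 input libraries differed by no more than the sampling noise and were counted as 1 sample, so values of the input are means of that pair without an SD. Of 20202 genes in the table, 10908 were tested. All 6 libraries carried the insert, so the insert itself was not compared with its absence.

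The comparison of HRDE-1 sRIP with input asks which genes' small RNAs were enriched or depleted in the HRDE-1 precipitate. The labels name no mock precipitation and none from an untagged strain. Carry-over of input RNA can therefore not be told apart from binding, in either precipitate. Small RNA against 22 of 36 oogenic genes and 60 of 81 ribosomal protein genes fell in the HRDE-1 precipitate. Camera placed both lists below other genes at a preset correlation. Neither passed with an estimated correlation (camera adjusted p = 0.377 for each), a test with 2 residual degrees of freedom that no list passed. That of cgh-1, a germline RNA helicase, fell from 78.7 RPKM in the input to 17.5 ± 0.477 (SD, n = 2). Of 13 targets of ERGO-1 class siRNA, which belongs to a separate Argonaute pathway, 11 fell (adjusted p = 0.377 with an estimated correlation), and C44B11.6 fell from 1304 RPKM to 120 ± 12.3 (SD, n = 2). Among the genes that rose were unc-119, a neuronal gene, from 35.1 to 89.2 ± 1.13 RPKM (SD, n = 2), and F02H6.2, from 10.4 to 45.2 ± 5.22 RPKM (SD, n = 2). limma called 780 genes higher and 1124 lower, each of them on the same side of the input in both replicates.

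Of the 8 largest rises, C53A3.3 had 12 reads in HRDE-1 and 0 in the input, so it was at least 2.48-fold higher. Y66A7A.3 had 15 reads against 1, a read ratio of 8.93 with a counting interval of 1.37 to 376. It was not matched to WBcel235, so these reads are minimum numbers and the interval holds only for them. T11F8.2, F02H6.2, C23F12.4, moc-1 (a gene of molybdenum cofactor synthesis), F53F8.3 and T02G6.5 had log2 fold changes of 2.11, 2.02, 1.97, 1.92, 1.88 and 1.88, with limma adjusted p from 0.00865 to 0.0179. Among the largest falls, F19G12.4 had 44 reads in the input and 0 in HRDE-1, at least 24.3-fold lower. T08B6.2, an ERGO-1 class target, fell from 145 to 3.56 ± 2.8 RPKM (SD, n = 2; log2 fold change −5.15 ± 0.56 SE, limma adjusted p = 0.00937). The F-box genes fbxa-52 and fbxa-61 had log2 fold changes of −5.02 ± 0.55 and −4.73 ± 0.23 (SE), and Y17D7B.4, Y47H10A.5, Y46D2A.1 and C18D4.4 had −4.86, −4.59, −4.37 and −4.33. On WBcel235, T08B6.2 lies on chromosome IV from 4894370 to 4897043 and F02H6.2 on chromosome IV from 14196476 to 14198802.

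In the HRDE-1 precipitate, 22 of 36 oogenic and maternal RNA regulators fell and 0 rose, also when adjusted over the list alone (median log2 fold change −1.07, camera adjusted p = 8.53e-09 and adjusted p = 0.377 with an estimated correlation). mex-1, a regulator of early embryonic cell fate, fell by 2.11, cpg-2, a proteoglycan of the eggshell, by 2.11 and cgh-1 by 2.10 on the log2 scale. The list's median was −0.98 within replicate 1 and −1.27 within replicate 2. Of 29 meiotic chromosome genes 5 fell, among them zim-3, a chromosome pairing protein, at −1.27, syp-4, a synaptonemal complex protein, at −1.14, and dsb-1, required for meiotic double-strand breaks, at −1.13. That list had a median of −0.77, with 5 lower and 0 higher also when adjusted over the list alone (camera adjusted p = 2.73e-06, and adjusted p = 0.377 with an estimated correlation). None of the 16 P granule genes was called (0 higher and 0 lower by limma, also adjusted over the list alone), although their median was −0.53 (camera adjusted p = 0.0157, and adjusted p = 0.421 with an estimated correlation). Among 46 Argonautes and small RNA pathway genes 5 fell and 0 rose, in both adjustments, with a median of −0.39 (camera adjusted p = 0.0213, and adjusted p = 0.602 with an estimated correlation). They included wago-4, an Argonaute, at −1.10, prde-1, a piRNA transcription factor, at −1.07, and eri-9 at −1.02. With library medians centred, wago-4, prde-1, eri-9, zim-3, syp-4 and dsb-1 stood at −0.71, −0.69, −0.63, −0.89, −0.75 and −0.75 and were no longer called. The eri-9 call was also lost with no filter on low values and with the median ratio to the input set to 0.

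Of 81 ribosomal protein genes 60 fell in HRDE-1 and 0 rose, also when adjusted over the list alone, with a median of −1.43 (camera adjusted p = 1.19e-14, and adjusted p = 0.377 with an estimated correlation). rpl-21 fell from 20.2 to 3.04 ± 0.537 RPKM, rps-25 from 30.8 to 5.59 ± 0.316 and rpl-13 from 26.3 to 4.76 ± 0.321 (SD, n = 2 each). Of 13 ERGO-1 class targets 11 fell in both adjustments, with a median of −3.0 (camera adjusted p = 9.54e-06, and adjusted p = 0.377 with an estimated correlation), and −2.71 and −3.13 within the replicates. W04B5.1 fell from 568 to 32.2 ± 7.72 RPKM (SD, n = 2). Of 51 spermatogenesis genes 12 fell and 1 rose, or 11 and 1 adjusted over the list alone, with a median of −0.49 (camera adjusted p = 0.00718, and adjusted p = 0.377 with an estimated correlation). Against 0 reads in HRDE-1, the nematode-specific genes nspd-7 and nspd-2 were at least 5.05-fold and 2.28-fold lower, and nspd-1 had a log2 fold change of −1.84, a call lost with no filter and with a pseudocount of 0.1. Of 7 germline genes inserted into Cer3 in this or another strain 3 fell, also adjusted over the list alone, namely rpl-1 at −1.60, zim-3 at −1.27 and mex-5 at −1.20 (list median −0.51, camera adjusted p = 0.0203, and adjusted p = 0.377 with an estimated correlation). The zim-3 and mex-5 calls were lost with library medians centred (−0.89 and −0.81).

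Markers of somatic tissues did not move together in HRDE-1. Of 10 intestinal genes 6 fell in both adjustments, from low levels. The list's median was −1.17 (camera adjusted p = 0.00242, and camera adjusted p = 0.421 with an estimated correlation). It was −1.23 with bounds in place of folds where the 2 genes at 0 in a group had one. Among the 6 genes, the yolk gene vit-5 had 1 read against 40, a read ratio of 0.0149 with an interval of 0.000368 to 0.0878. The lysozyme gene lys-4 had 2 reads against 9 (0.132, interval 0.0139 to 0.639), and asp-1, a protease gene, was at least 5.55-fold lower, and both calls were lost with no filter and with library medians centred. Of 14 neuronal genes 3 rose in both adjustments (list median 0.30, camera adjusted p = 0.0213, and camera adjusted p = 0.377 with an estimated correlation). They were unc-119 at 1.32, the synaptic vesicle gene sng-1 at 1.15 and the synapse assembly gene syd-2 at 1.06. The sng-1 value rests on 5 input reads, with ratios of 0.53 and 2.14 within the replicates. Without input replicate 2 it was 0.58. Among 34 collagen genes 2 rose and 0 fell, or 1 and 0 adjusted over the list alone (median 0.09, camera adjusted p = 0.132). Of 69 histone genes 10 fell and 0 rose in both adjustments, and the median of −0.20 turned to 0.19 with library medians centred (camera adjusted p = 0.213). Of 11 muscle genes 5 fell in both adjustments, and the median of 0.08 differed in sign from the mean of −0.56 and from the test (camera adjusted p = 0.512). Of 20 heat shock genes 6 fell and 0 rose, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.834), and the median of −0.08 turned to 0.31 with library medians centred.

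Of random lists matched on input level, 11.4% had a median as low in HRDE-1 as small RNA pathway genes, 45.3% as low as inserted germline genes and 19.41% as high as neuronal genes, against at most 1.82% for the other lists past the threshold. The split of calls between HRDE-1 and input rested on the scale. Of the calls 41.0% were higher with a median log2 fold change of all genes of −0.03, against 87.1% (2254 higher and 333 lower, median 0.35) with library medians centred and 49.1% (977 and 1013, median 0.01) with the median ratio to the input set to 0, and the medians of histone and heat shock genes were the list medians that changed sign. Centring library medians also brought several medians near 0, to −0.0071 for small RNA pathway genes, which then no longer passed the threshold, −0.10 for spermatogenesis, −0.14 for P granule and −0.13 for inserted germline genes. It moved meiotic genes from −0.77 to −0.38 and oogenic genes from −1.07 to −0.68. Neuronal genes did not pass the threshold with no filter on low values. With no filter on low values 491 genes were higher, with voom weights 1184, and with the HRDE-1 library of replicate 1 or 2 left out limma called 92 and 101 genes higher and 97 and 67 lower, and with either CSR-1 library left out 0 and 0 (5512 and 5508 genes had an unadjusted p under 0.05). Of the 42 named genes called in HRDE-1, these 4 omissions ended 31, 32, 42 and 42 calls, or 2, 3, 1 and 1 in the fit with 2 input samples. The latter were sng-1 under each, lys-4 without HRDE-1 replicate 1, and eri-9 and oma-2 without HRDE-1 replicate 2. Leaving out a CSR-1 library changed only the estimate of spread, since CSR-1 libraries do not enter the HRDE-1 fold changes. Without input replicate 1 the calls of lys-4 and syd-2 ended, and without input replicate 2 those of oma-2, prde-1 and sng-1. T11F8.2 was not called with no filter.

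**Figure D1:**
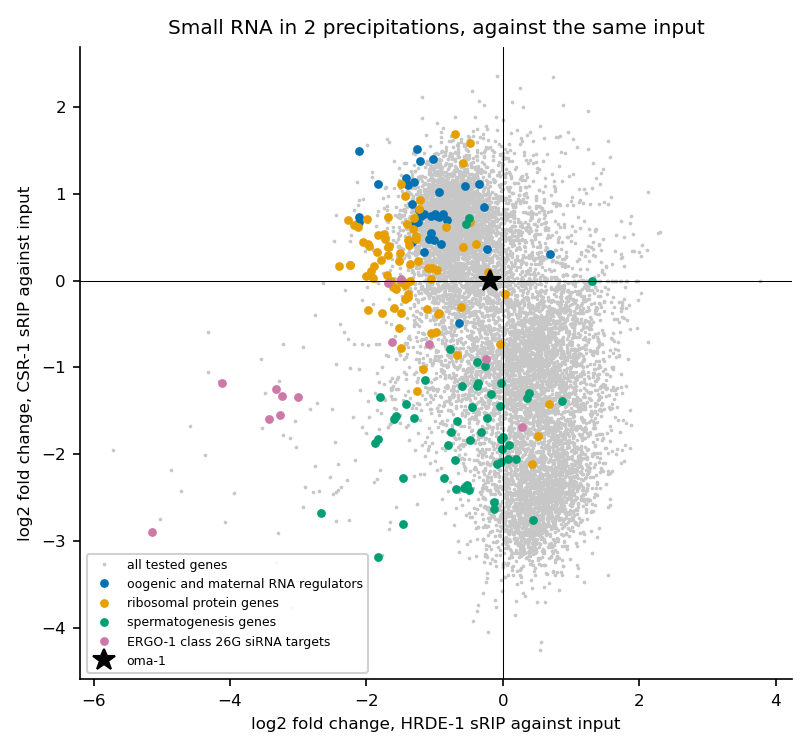
Each point is a tested gene, with its log2 fold change of HRDE-1 sRIP over input on the x axis and of CSR-1 sRIP over input on the y axis, and colours mark 4 of the gene lists. Oogenic genes had medians of −1.07 and 0.74 on the 2 axes and ERGO-1 class targets −3.0 and −1.24, while oma-1 (star) lay at −0.19 and −0.01 on the deposited scale and above 0 on both with library medians centred (0.20 and 0.45).

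The comparison of CSR-1 sRIP with input asks the same of CSR-1. Small RNA against 11 of 36 oogenic, 3 of 29 meiotic and 4 of 16 P granule genes rose in the CSR-1 precipitate, and that against 44 of 51 sperm and 23 of 34 collagen genes fell. Camera placed the first 3 lists above other genes and the last pair below at a preset correlation. With an estimated correlation, a test with 2 residual degrees of freedom, none passed (camera adjusted p = 0.39 for each of the first 3 and 0.313 for each of the pair). cpg-2 rose from 36.9 RPKM in the input to 106 ± 9.50 (SD, n = 2), and meg-1, a P granule protein gene, from 2.78 to 16.2 ± 0.715 (SD, n = 2). rde-11, a gene of the RNAi pathway, fell from 283 to 67.8 ± 12 RPKM (SD, n = 2). spe-41, which encodes a sperm calcium channel, fell from 39.4 to 5.0 ± 0.909 RPKM (SD, n = 2). limma called 778 genes higher, all of them on the same side in both replicates, and 4019 lower, of which 3989 were.

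T27A8.2 had the largest named rise, from 4.69 to 28.3 ± 4.52 RPKM (SD, n = 2; log2 fold change 2.36 ± 0.20 SE, limma adjusted p = 0.000874). sup-36, meg-1, Y111B2A.28, ndub-7, T09A5.4, Y18H1A.2 and C56G2.5 had log2 fold changes of 2.22, 2.18, 2.11, 2.07, 2.05, 2.02 and 1.99. C17C3.15 fell from 59.0 to 2.39 ± 1.81 RPKM (SD, n = 2; log2 fold change −4.26 ± 0.47 SE, limma adjusted p = 0.0018). F20B4.4, Y41E3.22 and C07D8.3 had log2 fold changes of −3.91, −3.85 and −3.80. D2024.10, H09I01.1, F39E9.10 and Y32G9A.11 kept 2, 3, 2 and 3 reads in CSR-1, with read ratios of 0.0367 (interval 0.00426 to 0.143), 0.0504 (0.00994 to 0.16), 0.0216 (0.00255 to 0.0818) and 0.0519 (0.0102 to 0.165). H09I01.1 and Y32G9A.11 were not matched to WBcel235, so their reads are minimum numbers and their intervals hold only for these. On WBcel235, T27A8.2 lies on chromosome X from 16057676 to 16058945 and C17C3.15 on chromosome II from 5570654 to 5572371.

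In the CSR-1 precipitate, 11 of 36 oogenic genes rose and 0 fell, also when adjusted over the list alone, with a median of 0.74 (camera adjusted p = 9.72e-10, and adjusted p = 0.39 with an estimated correlation), and 0.72 and 0.76 within the replicates. cpg-3 and cpg-2, proteoglycans of the eggshell, rose by 1.51 and 1.49 on the log2 scale, and pos-1, a maternal zinc finger gene, by 1.40. Of 29 meiotic genes 3 rose in both adjustments: lab-1, a chromatid cohesion gene, at 1.25, the cohesin gene him-1 at 1.12 and the BRCA1 ortholog brc-1 at 1.11 (list median 0.64, camera adjusted p = 2.49e-07, and adjusted p = 0.39 with an estimated correlation). Of 16 P granule genes 4 rose in both adjustments, including meg-1 at 2.18, meg-2 at 1.27 and the RNA helicase gene glh-2 at 1.11 (list median 0.61, camera adjusted p = 6.49e-05, and adjusted p = 0.39 with an estimated correlation). Argonautes and small RNA pathway genes went both ways, with 4 of 46 higher and 4 lower in both adjustments, a median of 0.41 and a mean of 0.15 (camera adjusted p = 0.000575, and adjusted p = 0.441 with an estimated correlation). The lower ones included the helicase gene eri-6 at −2.29, rde-11 at −2.06 and rrf-2, an RNA-dependent RNA polymerase gene, at −2.01.

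Of 51 spermatogenesis genes 44 fell in CSR-1 and 0 rose, also adjusted over the list alone. The list's median was −1.75 (camera adjusted p = 8.41e-06, and camera adjusted p = 0.313 with an estimated correlation). It was −1.56 with bounds in place of folds where the 29 genes at 0 in a group had one. nspd-1 was at least 7.35-fold lower, and ssp-16 had 1 read against 17, a read ratio of 0.0356 with an interval of 0.000852 to 0.227. Of 34 collagen genes 23 fell in both adjustments, with a median of −1.72 (camera adjusted p = 0.000207, and adjusted p = 0.313 with an estimated correlation). col-45, col-60 and col-157 had log2 fold changes of −3.15, −3.02 and −2.93. Of 69 histone genes 32 fell in both adjustments, with a median of −0.96 (camera adjusted p = 0.00169, and adjusted p = 0.39 with an estimated correlation), among them his-41 at −2.65, his-35 at −2.19 and his-22 at −2.18. Of 13 ERGO-1 class targets 8 fell in both adjustments (median −1.24, camera adjusted p = 0.0364, and adjusted p = 0.441 with an estimated correlation), among them T08B6.2 at −2.90, H16D19.4 at −1.68 and C44B11.6 at −1.59.

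On the deposited scale ribosomal protein genes were near the input level in CSR-1, with 4 of 81 higher and 5 lower, or 4 and 3 adjusted over the list alone (median 0.17, or 0.63 with library medians centred and 0.70 with the median ratio to the input set to 0, camera adjusted p = 0.000748, and adjusted p = 0.441 with an estimated correlation). rpl-37.1 rose by 1.68 on the log2 scale, while rpl-11.2 and rpl-42 had −2.11 and −1.79. Of 10 intestinal genes 1 fell, or 0 adjusted over the list alone, and the list's median of 0.55 lay above its mean of 0.17 (camera adjusted p = 0.0158, and adjusted p = 0.441 with an estimated correlation). The member called was mtl-2, a metallothionein gene, whose 3 input reads and 0 CSR-1 reads allow no fold. Of 14 neuronal genes 8 fell in both adjustments (median −1.07, or −1.15 with the gene at 0 in a group set to its bound, camera adjusted p = 0.111). Of 11 muscle genes 1 rose and 2 fell in both adjustments, with a median of 0.23 and a mean of −0.14 (camera adjusted p = 0.371). Of 20 heat shock genes 6 fell in both adjustments, and camera gave a rise (adjusted p = 0.522) although the median was −0.20, which turned to 0.26 with library medians centred. Of 7 inserted germline genes meg-2 alone was called, in both adjustments (list median 0.45, camera adjusted p = 0.0531).

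Of random lists matched on input level, 93.0% had a median as low in CSR-1 as ERGO-1 class targets, 9.17% as low as histone genes and 27.1% as high as ribosomal protein genes, against at most 0.23% for the other lists past the threshold. The split of calls between CSR-1 and input also rested on the scale. Of the calls 16.2% were higher with a median of all genes of −0.54, against 46.1% (2540 higher and 2969 lower, median −0.08) with library medians centred and 49.8% (2785 and 2810, median −0.01) with the median ratio to the input set to 0, and the median of heat shock genes was the list median that changed sign. ERGO-1 class targets passed the threshold under neither of these scalings, and inserted germline genes passed it under both and with no filter. Without the CSR-1 library of replicate 2, 491 genes were called higher. Of the 44 named genes called in CSR-1, 10 calls were lost without either HRDE-1 library and 7 without either CSR-1 library. In the fit with 2 input samples 0 were lost without either HRDE-1 library, meg-2 without CSR-1 replicate 1 and ssp-16 without CSR-1 replicate 2. The calls of T08B6.2, meg-2, mtl-2 and rpl-42 were lost with no filter, and those of H09I01.1, Y32G9A.11, meg-2 and mtl-2 with a pseudocount of 0.1. The mtl-2 call was also lost under both scalings and without input replicate 1. Reads that map to several genes were counted in a way not given in the sources used here, so values of histone, nspd, collagen, F-box and ribosomal protein genes with near-identical copies are uncertain.

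**Figure D2:**
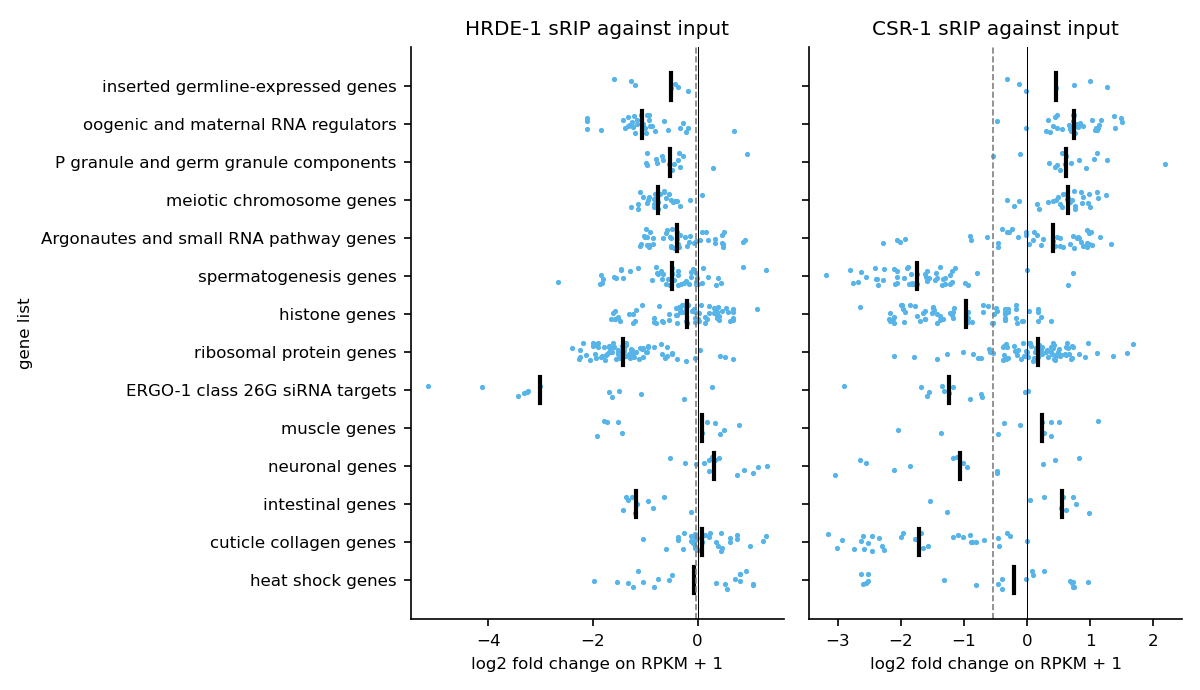
Each point is a gene of the list named at the left, placed at its log2 fold change on RPKM + 1 against input, with HRDE-1 sRIP in the left panel and CSR-1 sRIP in the right. Black bars are list medians (for example −1.43 and 0.17 for ribosomal protein genes) and dashed lines the medians of all tested genes, −0.03 and −0.54; the histone median in the left panel and the heat shock medians in both panels change sign with library medians centred.

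The direct comparison of HRDE-1 with CSR-1, a contrast chosen after the data were seen, asks how small RNA was divided between both precipitates. Small RNA of most oogenic, meiotic, P granule and ribosomal protein genes was higher in CSR-1, and that of most sperm, collagen and neuronal genes was higher in HRDE-1, while all 11 list calls were lost with an estimated correlation (adjusted p = 0.361 to 0.473). cpg-2 had 7.91 ± 1.88 RPKM in HRDE-1 and 106 ± 9.50 in CSR-1 (SD, n = 2 each), and unc-119 had 89.2 ± 1.13 and 8.94 ± 0.300 (SD, n = 2 each). limma called 4767 genes higher in HRDE-1 and 2901 lower, with a median log2 fold change of all genes of 0.60.

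Of 36 oogenic genes 32 were lower in HRDE-1 than in CSR-1, as were 23 of 29 meiotic, 12 of 16 P granule and 62 of 81 ribosomal protein genes, with medians of −1.78, −1.38, −1.38 and −1.64. Their camera adjusted p were 4.95e-10, 5.71e-08, 0.000371 and 1.07e-11, against adjusted p = 0.362, 0.362, 0.362 and 0.361 with an estimated correlation. Of 51 spermatogenesis genes 30 were higher in HRDE-1 and 2 lower. So were 27 and 0 of 34 collagen genes and 9 and 1 of 14 neuronal genes. These lists had medians of 1.33, 1.67 and 1.57. With genes at 0 in a group set to their bounds, where they had one, these lists had 0.95, 1.77 and 1.57. Their camera adjusted p were 0.00414, 7.42e-05 and 0.0453, against adjusted p = 0.361, 0.361 and 0.362 with an estimated correlation. Of random lists matched on input level 41.1% had a median as high as sperm genes, 4.47% as neuronal and 0.28% as collagen genes, and at most 0.55% had a median as low as the oogenic, meiotic, P granule or ribosomal protein genes. Neuronal genes did not pass the threshold with 2 input samples, with or without the replicate block, or with the median ratio to the input set to 0. None of these 7 medians changed sign with library medians centred or with the median ratio to the input set to 0.

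Further lists were lower in HRDE-1 than in CSR-1. Of 13 ERGO-1 class targets 9 were lower and 1 higher (median −1.66), of 10 intestinal genes 8 and 0 (−1.52, or −1.95 with genes at 0 in a group set to their bounds), of 46 small RNA pathway genes 20 and 5 (−0.81) and of 7 inserted germline genes 4 and 0 (−1.29). Their camera adjusted p were 0.00336, 0.00461, 0.000912 and 0.00754, against adjusted p = 0.362, 0.453, 0.473 and 0.361 with an estimated correlation. Of matched random lists 0.01%, the smallest share the draws can give, had a median as low as the ERGO-1 class targets or the intestinal genes, 1.9% as the small RNA pathway genes and 12.5% as the inserted germline genes. Histone, muscle and heat shock genes did not pass (camera adjusted p = 0.149, 0.428 and 0.669), with 30, 2 and 8 genes higher and 3, 5 and 7 lower, and for heat shock genes the median of 0.71 differed in sign from the test. Adjusted over the list alone, the counts of all 14 lists were the same except for intestinal genes, with 8 lower and 1 higher. The split was 62.2% higher, against 59.9% with library medians centred and 49.5% (3755 higher and 3835 lower, median 0.11) with the median ratio to the input set to 0.

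Both precipitations share the input, which ties their fold changes together. Across 10908 genes, which are not independent replicates, the fold changes against input had a Pearson r of −0.46, where unchanged precipitations simulated against the same input gave 0.594. The covariance was −0.461 against a simulated 0.0544, and 24.8% of genes had the same sign in both against a simulated 69.3%. Of the genes called in both, 434 were higher in HRDE-1 and lower in CSR-1 and 134 the reverse, where independent lists would share 287 and 80.2. A further 13 were higher in both and 160 lower in both, where independent lists would share 55.6 and 414. Unchanged precipitations simulated against the same input shared 0, 0, 0.08 and 0 calls on average in these 4 classes. With no gene changed few calls can arise, so these averages do not show how much overlap a shared input adds among the observed calls. The share of genes with the same sign and the counts in the 4 classes hold for the deposited scale only. They were not repeated under the other scalings, which change the calls. The input could not be divided into parts of 2 or more libraries, so the values were not repeated with separate inputs either. Among 10123 genes with an input RPKM of 1 or more, 449 had a log2 ratio to input of at least 1 in both HRDE-1 replicates but not in both of CSR-1, 490 the reverse, and 5 met both rules.

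oma-1 is the gene whose fragment Cer3 carries in this strain. Its small RNA was at similar levels in all libraries, with 33.1 and 30.3 RPKM in the input libraries, 27.7 ± 1.57 (SD, n = 2) in HRDE-1 and 31.5 ± 1.83 (SD, n = 2) in CSR-1, from 278, 403 and 449 reads. oma-2, its paralog, which acts with it in oocyte maturation, had 27.7 RPKM in the input, 13 ± 1.97 in HRDE-1 and 47.1 ± 5.58 in CSR-1 (SD, n = 2 each). On WBcel235, oma-1 lies on chromosome IV from 8888976 to 8890999 and oma-2 on chromosome V from 8029439 to 8031214. The values do not separate reads of the insert from reads of the endogenous gene, nor bound small RNA from carry-over of the input.

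oma-1 was called in no comparison, with log2 fold changes of −0.19 ± 0.12 for HRDE-1 and −0.01 ± 0.12 for CSR-1 against input (SE, limma adjusted p = 0.245 and 0.944) and −0.18 ± 0.10 between them (SE, limma adjusted p = 0.142). With library medians centred the first pair became 0.20 and 0.45, so its direction against input was not fixed. With the median ratio to the input set to 0 the difference between them became −0.67 (limma adjusted p = 0.000942, and up to 0.4 over all 18 alternatives), where the oogenic list had a median of −2.27. oma-2 fell by 1.05 in HRDE-1 (limma adjusted p = 0.0143) and stood at 0.74 in CSR-1 (limma adjusted p = 0.0186), or 1.2 and 1.27 and past the threshold under the 2 other scalings. Its HRDE-1 value was −0.66 and no longer called with library medians centred, and its call was also lost with no filter. With single libraries left out it lay from −0.90 to −1.19. In the fit with 1 input sample the call was lost in each such case except without input replicate 1, and in the fit with 2 input samples only without HRDE-1 replicate 2. hrde-1 and csr-1, the genes of the precipitated proteins, were not called either. hrde-1 had log2 fold changes of 0.05 in HRDE-1 and 0.10 in CSR-1 (limma adjusted p = 0.789 and 0.559), and csr-1 had −0.92 and 0.40 (limma adjusted p = 0.0101 and 0.0405).

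The other genes that were inserted into Cer3 in further strains were not inserted here and give the levels of their endogenous small RNA. mex-5, zim-3 and rpl-1 fell in HRDE-1 and had log2 fold changes of 0.74, 0.99 and −0.31 in CSR-1, none of them called. With library medians centred mex-5 and zim-3 were called there, as they were with the median ratio to the input set to 0. zim-3 was also called with a pseudocount of 0.1, with voom weights, and without input replicate 1 or CSR-1 replicate 1. him-5, him-8 and meg-2 had −0.51, −0.44 and −0.38 in HRDE-1 and 0.45, −0.12 and 1.27 in CSR-1. With library medians centred, meg-2 turned to 0.00082 in HRDE-1, and him-8 and rpl-1 turned to 0.34 and 0.15 in CSR-1. Of the soma-expressed genes, ida-1, a neuronal gene, had 0.21 in HRDE-1 and fell by 2.64 in CSR-1. ttm-2 had 0.41 in HRDE-1, and 2 reads in CSR-1 against 5 in the input gave a ratio of 0.242 with an interval of 0.0231 to 1.48, called only with voom weights. cah-4 and unc-22 lay below the filter, with 0 and 15 reads in the input.

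**Figure D3:**
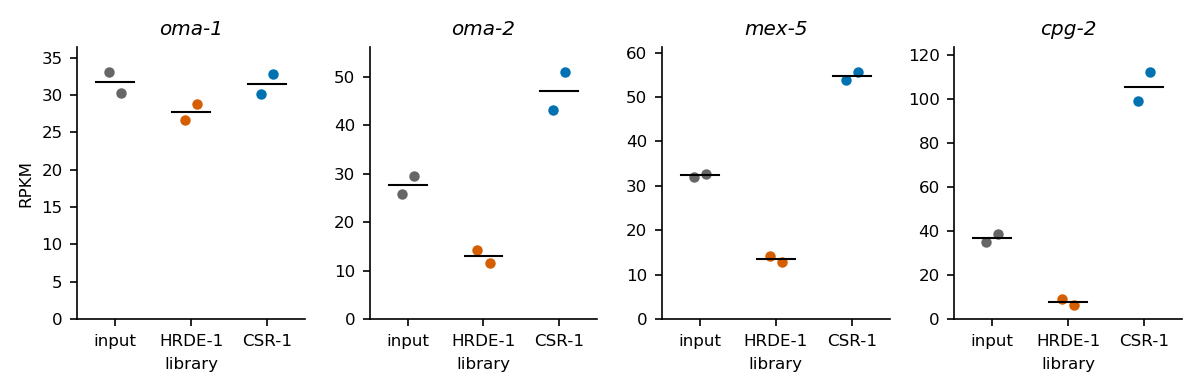
Points are RPKM of the single libraries and lines their means for oma-1, oma-2, mex-5 and cpg-2, with input, HRDE-1 sRIP and CSR-1 sRIP along the x axis. oma-1 had 27.7 RPKM in HRDE-1 and 31.5 in CSR-1, against 13 and 47.1 for oma-2 and 7.91 and 106 for cpg-2.

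Without the strand counted, reads of overlapping genes cannot be told apart. eri-6, brc-1, lab-1, cpg-3, rpl-37.1, D2024.10, Y41E3.22, T09A5.4, prde-1, mex-1, Y46D2A.1, F53F8.3, syd-2 and ttm-2 overlap a gene on the opposite strand. eri-6, his-41, C17C3.15, csr-1, W04B5.1, F19G12.4 and dsb-1 overlap a gene on the same strand. Y66A7A.3, H09I01.1, F20B4.4, C07D8.3, Y32G9A.11 and Y111B2A.28 were not matched to WBcel235.

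**Figure D4:**
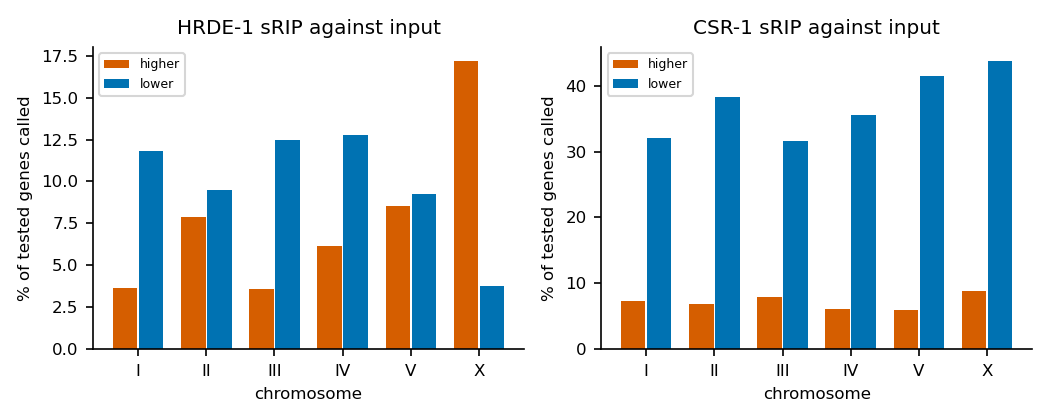
Bars give the percent of tested genes on each chromosome that limma called higher (orange) or lower (blue), for HRDE-1 sRIP on the left and CSR-1 sRIP on the right, each against input. On chromosome X 17.2% of genes were higher in HRDE-1, against 5.94% on the other chromosomes.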

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

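Merging the input pair, in place of the planned 2 input samples, was chosen only after the data were seen, as were the alternatives with every gene model, the median ratio to the input set to 0 and voom weights on deduced reads, and the contrast of HRDE-1 with CSR-1. Counts of genes stayed within 1.5 times the main ones except as follows. The 780 genes higher in HRDE-1 became 491 with no filter on low values, 2254 with library medians centred and 1184 with voom weights, and the 1124 lower became 333 with library medians centred. The 778 genes higher in CSR-1 became 2540 with library medians centred and 2785 with the median ratio set to 0. The changes under centring follow from moving all genes of a library by 1 constant, and the cause of the others was not tested. With single libraries left out, HRDE-1 gave 0 to 1045 genes higher and 0 to 1447 lower, and CSR-1 491 to 924 higher. The low ends of these HRDE-1 ranges arose where a CSR-1 library was left out of the fit with 1 input sample. CSR-1 libraries do not enter the HRDE-1 fold changes, which stayed the same (C18D4.4 −4.33, C23F12.4 1.97). Only the estimate of spread changed, which then rested on the HRDE-1 pair alone, so these lost calls mark no change in level. They do mark that the HRDE-1 calls of the main fit rested on a spread shared with the CSR-1 pair. That pair differed less than the HRDE-1 pair (chi-square per degree of freedom 1.07 against 2.04). Whether its smaller spread or the number of samples kept those calls was not tested. Lone samples were assumed to vary like the other groups. With 2 input samples the same omissions gave 908 and 906 genes higher in HRDE-1. oma-1 turned to 0.20 in HRDE-1 with library medians centred and to 0.45 and 0.52 in CSR-1 with library medians centred and with the median ratio set to 0, and it lay from −0.0714 to 0.0533 in CSR-1 with single libraries left out. Between HRDE-1 and CSR-1, oma-1 moved from −0.18 to −0.67 with the median ratio set to 0, with a limma adjusted p from 0.000942 to 0.4 over its 18 alternatives. hrde-1 in HRDE-1 lay from −0.0018 to 0.11 with single libraries left out. meg-2 turned to 0.00082 in HRDE-1 with library medians centred. him-8 turned to 0.34 and 0.41, and rpl-1 to 0.15 and 0.22, in CSR-1 with library medians centred and with the median ratio set to 0. Over all alternatives, 1577 values of named genes other than oma-1 kept their direction and side of the threshold, 224 fell short of the threshold, 12 passed it newly and 6 reversed. With an estimated correlation 0 of the 10 lists past the threshold in HRDE-1 stayed past it, 0 of 10 in CSR-1 and 0 of 11 between them. That version rests on 2 residual degrees of freedom, so its losses neither show nor exclude that correlation between genes was the reason.

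The replicate numbers were not shown to pair the samples, since deviations of same-numbered libraries correlated at 0.0233, 0.00434 and 0.0333. With the replicate number as a block and 2 input samples, limma called 940 genes higher and 1159 lower in HRDE-1 and 826 and 4068 in CSR-1. Not run, because the table of the other 45 samples was not used here, were the alternatives planned for inserted genes, oma-1 deletion, P granule, Argonaute and piRNA pathway mutants and CSR-1 depletion. Depth limits genes with few reads, such as C53A3.3 and mtl-2.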

Other observations

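The tests by chromosome, the rank of oma-1 among other genes, its differences from oma-2 and from counting error, and the shift of all genes for ERGO-1 class targets were chosen only after the results were seen. Genes higher in the HRDE-1 precipitate were more frequent on chromosome X than elsewhere. Of 1171 tested X genes 201 were higher (17.2%), against 562 of 9456 on other chromosomes (5.94%), an odds ratio of 3.28 (Fisher's exact test, adjusted p = 1.18e-33 over 24 tests). Of the X genes 44 were lower (3.76%), against 1053 of the 9456 elsewhere. Among the named genes that rose, moc-1, C23F12.4, sng-1 and syd-2 lie on X. T02G6.5, F53F8.3, F02H6.2, T11F8.2, C53A3.3 and unc-119 rose too and lie on other chromosomes. Of the named genes that fell, F19G12.4, fbxa-52 and vit-5 lie on X. Chromosomes I and III had fewer genes higher in HRDE-1, 3.64% and 3.57%, with odds ratios of 0.434 and 0.427 (Fisher's exact test, adjusted p = 3.34e-12 for each). In CSR-1, 43.7% of X genes were lower, against 35.8% elsewhere (Fisher's exact test, odds ratio 1.39, adjusted p = 7.42e-07), and 8.88% were higher, against 6.85% elsewhere (Fisher's exact test, odds ratio 1.32, adjusted p = 0.0265). Fisher's exact test takes genes as its units, and genes are not independent replicates. These p-values hold no spread between samples and serve only to describe the tested genes.

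The excess of X genes in HRDE-1 may reflect other properties of X genes, whose median input was 3.57 RPKM against 17.6 on other chromosomes. The tables argue against input level as the whole cause, since stratified by deciles of input RPKM the odds ratio was 2.39 (95% interval 2.0 to 2.84). They argue against the deduced model length too, since stratified by its deciles the odds ratio was 3.56 (95% interval 2.99 to 4.26). Of models above 0 with an annotated coding length only 23.2% had a final length equal to it. The true length is therefore not excluded. In 7 settings of scale, filter, pseudocount and weighting the odds ratio ran from 2.53 to 3.36. The design holds no group that bears on X, so no biological explanation was tested and the pattern stays a hypothesis.

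ERGO-1 class targets were low in both precipitates, and input level may account for that in CSR-1 but not in HRDE-1. Both list results were lost with an estimated correlation (camera adjusted p = 0.377 in HRDE-1 and 0.441 in CSR-1). In HRDE-1 their median of −3.0 was reached by 0 of 10000 random lists matched on input RPKM, 0.01% being the smallest share the draws can give. In CSR-1, 93.0% of such lists had a median as low as −1.24, as the random lists had a median of −2.21. With the median ratio to the input set to 0, the CSR-1 median was −0.71, with 11 of 13 genes below 0. Removing a shift of all genes between CSR-1 and input libraries thus did not bring the median to 0. The SE of 0.211 is taken over genes, which are not independent (estimated correlation 0.229). The list also did not pass the camera threshold at this scale, so a shift is not excluded. Binding by another Argonaute stays open, as no precipitate of one was compared.

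oma-1 differed less between HRDE-1 and CSR-1 (−0.18, or −0.67 with the median ratio to the input set to 0) than oma-2 and most oogenic genes. Reads shared between both paralogs would draw their fold changes together, yet these lay 1.61 apart (SE 0.177). Sharing would also draw oma-1 towards oma-2, which at −1.79 lay at the median of the other 35 oogenic genes. The values therefore argue against sharing as the cause of the pattern, although the amount of sharing was not tested. Counting error is too small, since the 95% interval of the oma-1 read ratio ran from −0.38 to 0.02 on the log2 scale, above the median of −1.79 of the other 35 oogenic genes. Of those 35 genes 2 (nos-2 and glp-1) lay as high as oma-1, which is part of the pattern and supports no explanation. Small RNA made from the Cer3 insert and bound by HRDE-1 was not tested and cannot be told apart from a property of endogenous oma-1, because 0 libraries lacked the insert.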
